A study of Escherichia coli with 5 samples.

How the data were processed

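Sheared genomic DNA of 5 mutant strains of E. coli MG1655 and of the wild type was labelled with Cy dyes and hybridised on spotted arrays, 1 array per strain. Per the labels, cultures were grown at 37 °C in LB with chloramphenicol, to an optical density of 1.7 to 1.8, and on all 5 arrays the mutant carried Cy5 and the wild type Cy3.

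The values used are the submitters' own. The deposited table holds 1 log2 ratio per spot and array. Its log base was taken from the values, which share a ceiling of 16.61, the binary logarithm of a round ratio. Scanner, background correction, scaling and genome build are not given in the sources used here. The deposited arrays were not centred on a common median, as their unequal medians show. The direction of the ratio is taken from the dyes in the labels, with 1 exception given in the results. Spots at the ceiling (103 in creB flhDC, 41 in crp flhDC, 15 in crp, 51 in fnr flhDC and 51 in fnr) were treated as having no value, a choice made after seeing the data.

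Spots were named through the platform annotation for these spots. Of 14400 spots 6412 had 1 gene name, 48 had several and 7940 had none. Of the first kind 6394 were matched by gene identifier to the RefSeq annotation of assembly ASM584v2, which gave 3197 genes, and 18 were not matched and were left out. No gene was named from a spot with several names. That annotation was used only for current names and for the order of genes along the chromosome, and no coordinates are given because the sources name no build. Spot names were used for an array only where its 2 spots per gene correlated at r of 0.3 or more, a rule set after seeing the data, and 2 arrays did not reach it.

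Each array was centred on the median of its named genes, with no loess or quantile step. A gene's value is the median over its spots. Repeat-spot SDs were 0.06 in the array labelled crp, 0.08 in fnr flhDC and 0.06 in fnr. A gene was called low or high at a log2 ratio of -1 or lower or 1 or higher. A run was 3 or more consecutive measured low genes with at most 1 gene above the limit inside, and its median was set against all windows of the same length. Gene lists fixed before the data were examined were the targeted genes and their neighbours (3 on either side), flhDC and the genes on both sides of it, flagellar genes elsewhere, unlinked chemoreceptors, insertion sequence genes, 8 prophages, araC, araBAD and ribosomal proteins. List medians were compared with 10000 random lists of the same size. These were drawn from all measured genes of the array and were not matched for position on the chromosome. The segment with the largest difference in mean between inside and outside, relative to its standard error, was found by a scan. It covered all intervals of at least 50 genes and was added later. Distance from the origin was measured from the point between mnmG and mioC, in 10 bins of genes.

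The genes named are those of a rule fixed before the data were examined: the 3 targeted genes, low members of the lists around them and around flhDC, the ends of each run with the first measured gene beyond, and the 5 lowest and 5 highest genes per array outside runs. The genes trpS, uspC, otsA, tyrP, wbbK and yhcD were named after their values were seen, as were the genes of the closing section.

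The 3 strains labelled flhDC were compared with the other 2 by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment) and by an exact permutation test of list medians. Tested on simulated arrays of 3197 genes for that comparison, limma recovered 90.0% of 100 genes lowered by 1 and 100% of 100 genes lowered by 2 on the log2 scale, and called 0 unchanged genes. In the simulation the same genes were lowered equally in all 3 labelled arrays, with independent normal noise. These shares do not apply to the deposited names, which 2 of those arrays did not bear out. The run finder placed 100 of 100 simulated runs of 5 genes with both ends right, and the segment scan 97 of 100 simulated segments to within 1 gene.

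For the closing section the order of spots on the creB flhDC and crp flhDC arrays was estimated, after seeing the data. Spots fall into 48 blocks of 300 positions. Positions that repeat each other were paired by maximum-weight matching (networkx 3.6.1) on rank correlations over blocks, and the 150 pairs of these arrays were assigned to those of the named arrays by the best total rank correlation (scipy 1.17.1). Genes around flhDC and the 3 targeted genes were masked in the assignment, but not in the pairing of positions, which used both arrays together. Several versions of the score were compared by how often 2 separate comparisons agreed, and the values of the masked genes had been seen before the version was fixed. Pairs scoring above the 99% quantile of 100 random block orders were kept. On arrays shuffled in a known way, 55 pairs passed this limit and 55 of them were placed where they came from. The shuffled arrays were fnr and crp, placed against fnr flhDC, and all of these bore out the same spot names. The check thus does not give the error rate for creB flhDC and crp flhDC.

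Alternatives changed the limits, the centring, the scaling, the summary over spots, the run rules, the set of genes, the arrays included and the limma options. Spots with no name entered only the deposited medians and spot counts, the centring on all spots, the estimated order of spots and correlations between arrays over such spots. Left out of results under deposited names, apart from the check of repeat spots and the comparison of 3 strains with 2, were the creB flhDC and crp flhDC arrays. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.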

Results

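Genomic DNA of 5 Escherichia coli K-12 strains was compared with that of their parent, the wild-type strain MG1655, by comparative genomic hybridisation on spotted 2-colour arrays. In this assay a gene that is missing from the mutant gives a low ratio of mutant to wild-type signal. Each mutant carried a chloramphenicol resistance cassette in place of 1 regulatory gene, inserted with the phage lambda Red recombination system. The replaced gene was creB, the response regulator of a carbon-source sensing pair, in 1 strain. It was crp, the cyclic AMP receptor protein, in 2 strains, and fnr, the regulator of anaerobic metabolism, in the other 2. The strain labels added flhDC, the master regulator of flagellar genes, for 3 strains (creB flhDC, crp flhDC and fnr flhDC) and not for the other 2 (crp and fnr). Every strain was hybridised once, so no value below has a replicate check, and the number of arrays limits the precision.

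Each array held 14400 spots, of which 439 had no value in the creB flhDC array, 954 in crp flhDC, 840 in crp, 660 in fnr flhDC and 613 in fnr. The deposited log2 ratios had array medians of 0.65 for creB flhDC, 0.61 for crp flhDC, 0.16 for crp, -0.27 for fnr flhDC and -0.40 for fnr. After centring on the median of the named genes, the robust SD across genes was 0.35 in the array labelled crp, 0.14 in fnr flhDC and 0.14 in fnr.

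All 3197 genes that could be named were represented by 2 spots, and these tested whether the spot names fitted each array. Both spots of a gene gave closely similar ratios in the array labelled crp (Pearson r = 0.951 across genes), in fnr (r = 0.611) and in fnr flhDC (r = 0.530). They were unrelated in creB flhDC (r = 0.0119) and in crp flhDC (r = -0.0330). The 2 spots differed by 0.5 or less for 99.9% of the genes in the array labelled crp, 98.7% in fnr flhDC and 99.9% in fnr, against 77.7% in creB flhDC and 54.6% in crp flhDC. Under the deposited names gene values are therefore given for 3 arrays only, and under these names the creB flhDC and crp flhDC arrays entered only the comparison of 3 strains with 2. Genes are not independent replicates, so these correlations describe the arrays.

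**Figure D1:**
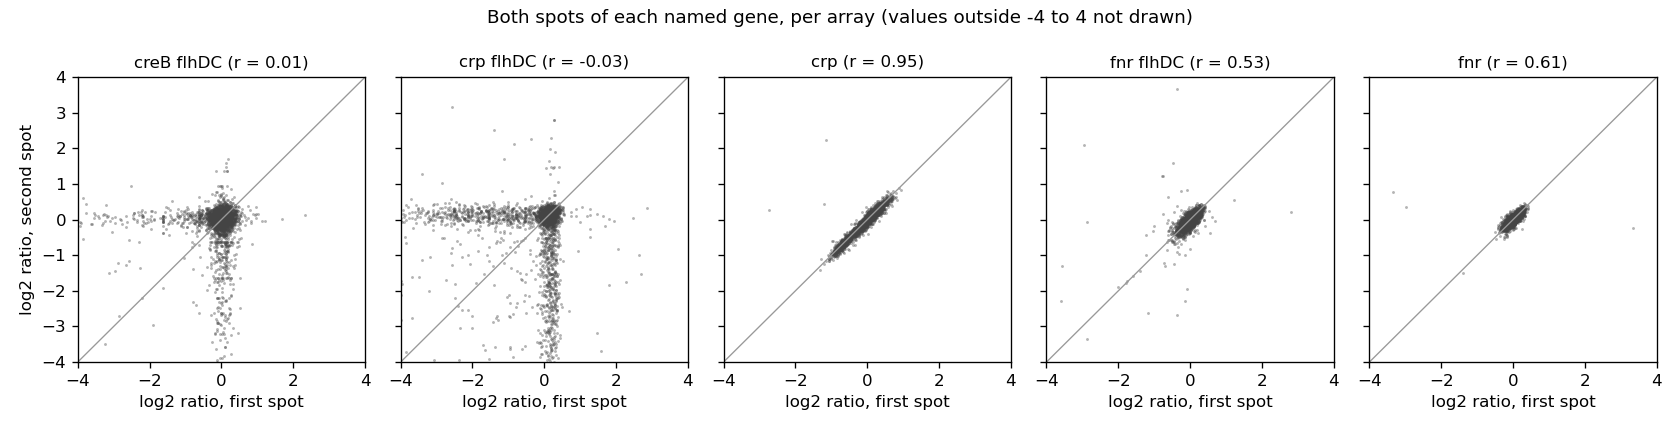
Log2 ratio of the first spot (x axis) against the second spot (y axis) of each named gene, centred on the array's median, with 1 panel per array and a grey line where both are equal. Points follow the line in the arrays labelled crp (r = 0.951), fnr flhDC (r = 0.530) and fnr (r = 0.611), and form a cross in creB flhDC and crp flhDC, where a low first spot goes with a second spot near 0 and the reverse.

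The targeted genes were read first, as a check of the strain labels. The fnr gene was at a log2 ratio of -1.42 in the fnr flhDC array, with spots at -1.40 and -1.45, and at -1.44 in the fnr array, with both spots at -1.39 or lower. It ranked 17th from the lowest of 3192 genes in fnr flhDC and 2nd of 3191 in fnr, and its 5 measured neighbours stayed near 0, with medians of 0.10 and 0.09. In the array labelled crp, the crp gene went the other way. It stood at 0.76, with spots at 0.71 and 0.80, and was the 4th highest of 3191 genes, while its 5 measured neighbours had a median of 0.15. With the sign of that array turned, crp would be at -0.76. The direction of the array labelled crp is thus not settled, and its values are given as deposited. The creB gene was at 0.11 in the array labelled crp, -0.10 in fnr flhDC and -0.23 in fnr.

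The fnr strains with and without flhDC in the label differed most clearly in a stretch of motility and chemotaxis genes next to flhDC. Going towards flhDC, the fnr flhDC array had log2 ratios of -1.58 for tar, the aspartate chemoreceptor, -1.78 for cheW, its coupling protein, and -3.11 for cheA, the chemotaxis histidine kinase. They were -1.95 for motB and -1.74 for motA, the stator proteins of the flagellar motor. In the fnr array the same genes lay between 0.11 and 0.19, and in the array labelled crp between 0.13 and 0.35. These 5 genes formed the only run of low genes found in the 3 arrays, with a median of -1.78. Of 3188 windows of 5 consecutive measured genes in the fnr flhDC array, 3 had a median as low: the run itself and the 2 windows shifted from it by 1 gene. The stretch ended sharply at the gene beyond tar: tap, the dipeptide chemoreceptor, was at 0.12. At the other end flhC, the measured member of the flhDC operon, was at -0.52, with spots at -0.44 and -0.60, and at 0.11 in fnr. No spot of the array was named for flhD. On the far side of flhDC, uspC was at 0.14 and otsA at 0.01, while tyrP, farther out, had 1 spot, at -0.95 (0.12 in fnr).

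**Figure D2:**
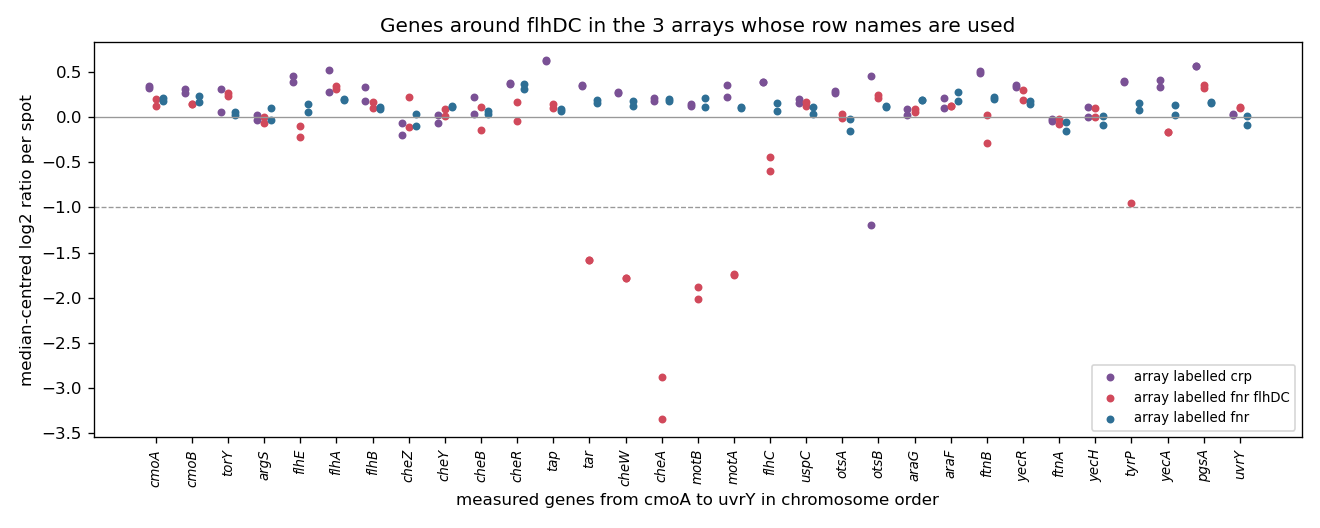
Median-centred log2 ratio of each spot (y axis) for the measured genes from cmoA to uvrY in chromosome order (x axis), in the arrays labelled crp, fnr flhDC and fnr. The dashed line marks -1. Only in fnr flhDC do both spots of the genes from tar to motA lie below it, with cheA lowest at -3.11, while flhC is at -0.52 and tap at 0.12.

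By fixed list, 5 of the 13 measured members of the mot, tar and flhB operons were at -1 or lower in fnr flhDC and 0 in fnr. The other members, from tap to flhE, lay between -0.16 and 0.33 in fnr flhDC. The median difference of this list between fnr flhDC and fnr was -0.26, below all of 10000 random lists of the same size, and its mean difference was -0.87. The 4 measured genes beyond flhE had a median difference of -0.05 and the 13 on the other side of flhDC, of which 1 (tyrP) differed by -1 or lower, one of 0.07, at the 23.6th and 97.8th percentiles of random lists. Flagellar genes elsewhere on the chromosome did not follow the stretch next to flhDC: the median difference was 0.00 for 14 genes of the flg cluster (46.1st percentile) and -0.02 for 17 of the fli clusters (27.4th percentile). The label flhDC was given by the submitters from these same arrays, so it is not independent evidence of a direction.

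Few genes were past a log2 ratio of -1 or 1 in the fnr arrays. In fnr flhDC 22 genes were at -1 or lower, 17 of them outside the run, and 3 at 1 or higher; in fnr these counts were 5 low and 2 high genes. Of the 22 low genes 10 had spots that differed by more than 0.5 and 5 had a single spot; of the 5 in fnr, 2 and 2. Only 7 of the 22 low genes in fnr flhDC had 2 spots within 0.5 of each other. They were fnr, the 5 genes of the run, and trpS, for tryptophanyl-tRNA synthetase, at -1.12 (-0.06 in fnr). In the fnr array fnr itself was the only low gene of this kind, and no high gene had agreeing spots in either array. The 5 lowest genes of fnr flhDC outside the run were yebO (-3.64), betB (-2.95), yeaV (-2.94), phoU (-2.84) and yphF (-2.43). The genes yebO, betB and phoU had a single spot, and the spots of yeaV and yphF differed by more than 0.5. Both spots of yeaV and of yphF were still at -1 or lower, as in 10 genes of this array. The 5 highest were mmuM (1.80), rplW (1.66), yahJ (1.51), mcrC (0.88) and ddlB (0.85). In fnr the lowest were mcrC (-2.82), fnr, yqiJ (-1.39), yahJ (-1.31) and casA (-1.29), and the highest endA (1.94), mmuM (1.56), ydjZ (0.40), tqsA (0.39) and serC (0.39).

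In the array labelled crp the largest feature was a long segment of the chromosome rather than a run of low genes. From wbbK to yhcD, 865 measured genes had a median log2 ratio of -0.59, against 0.11 for the other measured genes, a difference of -0.70 (0.70 with the sign turned). The step was sharp at both ends. The 50 genes before wbbK had a median of 0.29 and the first 50 inside -0.36. The last 50 inside had a median of -0.65 and the 50 beyond yhcD one of -0.02. Inside the segment 99.8% of the genes were below 0, against 31.5% outside; with the sign turned these are the shares above 0. The same genes differed from the rest by -0.01 in fnr flhDC and by -0.01 in fnr. The search for the segment was added after the data had been seen, since the planned runs at -1 returned 0 in this array.

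The segment also held most of the array's low genes. Of 19 genes at -1 or lower in the array labelled crp 15 lay in it, and 0 genes were at 1 or higher; with the sign turned these are 19 high and 0 low genes, and the lowest and highest genes change places. Without centring the array had 3 low and 19 high genes, and at 4 robust SDs 1 low gene. As deposited and centred, the 5 lowest genes were metN (-1.61), maeB (-1.37), yqiJ (-1.35), mcrC (-1.30) and fecD (-1.25). Of these only maeB, encoding a malic enzyme, had 2 agreeing spots, and metN, yqiJ and mcrC had 1 spot each. The 5 highest were rspB (0.89), marB (0.89), sapA (0.79), crp and ydgD (0.73), each with 2 agreeing spots.

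**Figure D3:**
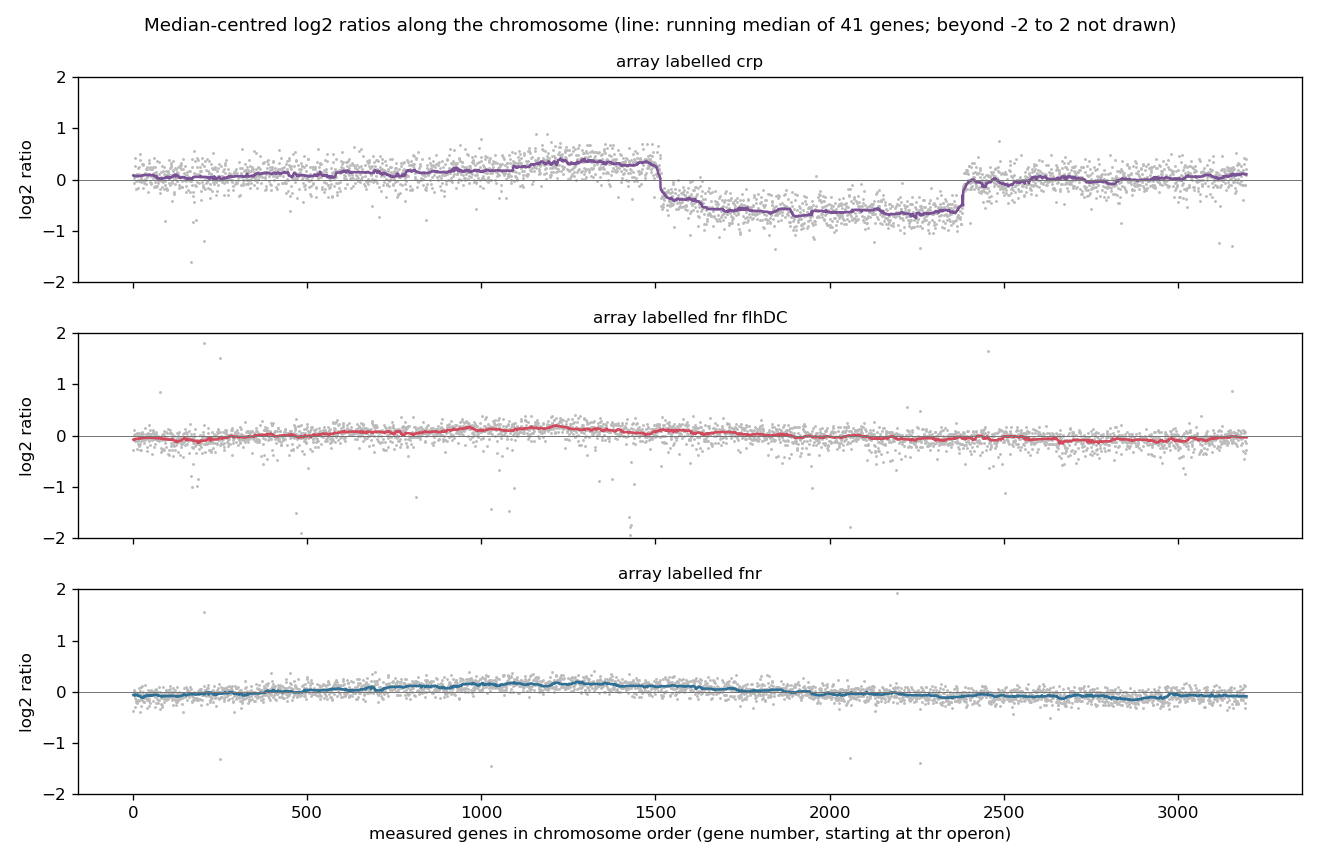
Median-centred log2 ratio of each gene (grey points, y axis) for all measured genes in chromosome order (x axis, gene number), with a running median of 41 genes as a coloured line, in the arrays labelled crp, fnr flhDC and fnr. The array labelled crp drops by 0.70 over 865 genes, and the fnr arrays bend gently, with values higher far from the replication origin.

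A smaller trend followed distance from the replication origin. Across genes, the Spearman correlation between log2 ratio and distance from the origin was 0.498 in fnr flhDC, 0.653 in fnr and 0.288 in the array labelled crp, or -0.288 with its sign turned. Of 10 bins of genes, the one nearest the origin had a median of -0.08 in fnr flhDC and -0.10 in fnr, and the one farthest from it 0.14 and 0.15. In the array labelled crp these medians were 0.00 and 0.27, and the lowest bin, at -0.32, lay midway, where the segment fell; with the sign turned the farthest bin is at -0.27 and the midway bin, at 0.32, is the highest. All arrays shared the wild-type reference strain, and part of any agreement between them may come from it. Pearson correlations across genes were 0.332 between fnr flhDC and fnr, 0.181 between crp and fnr and 0.0190 between crp and fnr flhDC. Spearman correlations were 0.612, 0.225 and 0.129. With the sign of the array labelled crp turned, its correlations with fnr and fnr flhDC become -0.181 and -0.0190 (Spearman -0.225 and -0.129).

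The prophages CPS-53 (9 measured genes) and the one that begins with intA (16) lie wholly inside the segment and had medians of -0.73 and -0.56 in the array labelled crp, at the 0.01st and 0.03rd percentiles of random lists (0.73 and 0.56, at the top of the random lists, with the sign turned), against 0.03 and -0.07 in fnr flhDC and 0.04 and -0.08 in fnr. The Qin prophage (22 genes) had medians of 0.34, 0.14 and 0.10 in crp, fnr flhDC and fnr, and Rac (16 genes) 0.16, 0.15 and 0.13. As deposited, the other prophages had medians near or above 0: e14 (0.08, 0.03 and 0.07), DLP12 (0.10, -0.01 and 0.01), CP4-6 (0.04, -0.05 and -0.01) and the prophage that carries flu (0.18, 0.07 and 0.07), in the same order. With its sign turned, the array labelled crp gives -0.08, -0.10, -0.04 and -0.18 for these. For Qin it then gives -0.34 and for Rac -0.16. The only prophage genes past 1 in either direction were in CP4-6, 1 in each array. Ribosomal protein genes (54) had medians of -0.14, -0.06 and -0.06, at or below the 1.66th percentile in each array as deposited. With its sign turned the array labelled crp gives 0.14, at the 98.3rd percentile. Random lists were not matched for distance from the origin, and the bin nearest it had medians of -0.08 in fnr flhDC and -0.10 in fnr. These percentiles were thus not separated from the trend with that distance. The flg cluster stood at 0.12, 0.08 and 0.07 and the fli clusters at 0.33, 0.03 and 0.08. Unlinked chemoreceptor genes (tsr, trg and aer) were at -0.01, 0.00 and -0.08, the 9 measured insertion sequence genes at 0.00, 0.01 and -0.06, and araBAD at -0.07, 0.03 and -0.06. The gene araC, which the Red helper plasmid carries, had a value only in fnr flhDC, at -0.37. Neighbours of the 3 targeted genes (16) had medians of 0.18, 0.05 and 0.01, with means of 0.15, -0.06 and -0.01. The mot, tar and flhB operons had medians of 0.28, -0.02 and 0.12. With its sign turned, the array labelled crp gives -0.28 for them, at the 0.175th percentile of random lists. The fli clusters are then at -0.33, at the 0.01st percentile. As deposited, the 50 measured genes before wbbK stood at 0.29 in that array, close to these lists. Random lists ignored position on the chromosome, so these percentiles do not set the motility genes apart from other genes on that side of the segment. Genes beyond flhE stood at 0.23, 0.15 and 0.12, and genes on the other side of flhDC at 0.18, 0.07 and 0.12.

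The planned comparison of the 3 strains with flhDC in the label against the 2 without used all 5 arrays with the names as deposited. With limma, 0 of 3194 genes were lower and 0 higher at a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.849. With the targeted gene as a block, which pairs the labelled and unlabelled strain within crp and within fnr over 4 arrays, limma gave 0 lower and 0 higher genes (smallest adjusted p = 0.850). Without the block, at an unadjusted p under 0.05, 7 genes were lower and 6 higher, but 214 were lower without fnr flhDC and 315 higher without fnr. Under these names tar had a difference of -1.14 (limma adjusted p = 0.849) and cheA one of -1.17 (limma adjusted p = 0.849). For the list of the mot, tar and flhB operons the labelled strains averaged 0.03 and the unlabelled 0.20, a difference of -0.17 (1-sided exact permutation p = 0.2 over 10 splits, where the smallest possible p is 0.1). Without centring it turned to 0.14 (exact permutation p = 0.7), and with 1 array left out it ranged from -0.25 to -0.09. The same exact permutation test gave p = 0.2 for flhC (difference -0.39), p = 0.1 for the genes on the other side of flhDC (-0.29), p = 0.3 for the flg cluster (-0.04) and p = 0.2 for the fli clusters (-0.16). Both arrays of crp strains entered with signs as deposited, although the direction of the one labelled crp is not settled. These differences were not computed with the signs turned. Because the repeat spots of creB flhDC and crp flhDC did not bear out their spot names, this comparison mixes genes and does not describe those strains. The crp pair could not be compared gene by gene for the same reason.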

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

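All tests of explanations in this part were chosen after the results they bear on were seen. None of the differences between strains given here was tested, since each strain has 1 array.

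The crp gene was at 0.76 in the array labelled crp, opposite in sign to fnr in both fnr strains (-1.42 and -1.44). The run from tar to motA had a median of -1.78 in fnr flhDC and 0.16 in fnr. In the creB flhDC and crp flhDC arrays, whose spot names were not used, an estimated order of spots gave 7 genes at -1 or lower in both spots of creB flhDC and 6 genes at 1 or higher in both spots of crp flhDC.

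Repeat spots disagreed in the creB flhDC and crp flhDC arrays when paired by the deposited names. Random noise is argued against: repeat positions learned in alternate blocks of these arrays correlated in the blocks left out, at r = 0.542 in creB flhDC and 0.701 in crp flhDC, against -0.0191 and -0.0342 for the deposited pairs. Another order of spots than the deposited one may be the cause. A pair of separate comparisons, of crp flhDC with crp and of creB flhDC with the fnr arrays, placed 76 of 150 position pairs alike, against at most 4 in 100 random block orders. No biological explanation was tested, since a strain cannot change where spots lie.

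The crp gene was high, not low, in the array labelled crp. A ratio written as wild type over mutant with the dyes as labelled would turn dye and background effects over too, yet over spots with no name this array correlated with fnr at a Spearman rho of 0.588 (0.644 between the fnr arrays); that reading assumes that such spots mostly carry those effects. More copies of the region around crp are argued against by its neighbours, whose median minus the value of crp was -0.61. Mutant and wild type may have been exchanged between the dyes in the arrays of crp strains: crp was also high, at 1.01, in crp flhDC under the estimated order of spots. An extra copy of crp alone stays open and was not tested.

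The segment from wbbK to yhcD was lower by 0.70 in the array labelled crp, or higher in the mutant if the dyes were exchanged. Unevenness over the slide is argued against by 1134 pairs of spots next to each other in the deposited order. There the spot from the segment differed by a median of -0.69. That reading assumes that the deposited order follows the slide, which the sources do not say. A replication gradient is argued against by genes at the same distances on the other arm, from which the segment differed by -0.68. A change of copy number between 2 copies of an insertion sequence is a candidate explanation: both ends fall in gaps between measured genes that hold an insH gene of IS5 (insH7 and insH10). Counting every kind of insertion sequence gene, 2.14e-05 of random pairs of the 3190 gaps share one, a value that understates chance because the idea came from the ends themselves. The crp flhDC strain may carry such a change too. Position pairs were learned from creB flhDC and crp flhDC together, so crp flhDC values entered the pairing. With these pairs placed from creB flhDC alone, 37 passed, which gave 197 genes inside the segment and 385 outside. In crp flhDC the segment then differed by -0.18, as low as in 2 of 1000 exchanged placings. Misplaced pairs could shrink this value, so its size cannot be set against that in the array labelled crp. With the same pairs placed from crp flhDC alone, the segment differed by 0.00 in creB flhDC. A change acquired in the wild-type culture stays open.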

How the results depend on the processing

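The run from tar to motA was found in fnr flhDC under all 11 alternatives with the same 5 genes, and the fnr array had 0 runs under each. Keeping spots at the ceiling, centring on all spots, requiring 2 agreeing spots and using the estimated order of spots were chosen after seeing the data; the other alternatives were fixed before. The cause of these shifts was not tested. In the array labelled crp 0 runs became 33 at a limit of 0.7, all inside the long segment, and 1 (pdxB to flk) with a minimum of 2 genes. Its 19 low genes became 272 at a limit of 0.7, 1 at 1.5, 1 at 4 robust SDs, 1 with scaled arrays, 3 without centring and 7 when centred on all spots. Its 0 high genes became 8 at a limit of 0.7, 19 without centring, 1 with ceiling spots kept and 2 when centred on all spots. In fnr flhDC 22 low genes became 37 at 4 robust SDs, 34 with scaled arrays and 7 with agreeing spots, and 3 high genes became 5 at a limit of 0.7, 5 at 4 robust SDs, 5 with scaled arrays and 0 with agreeing spots. In fnr 5 low genes became 1 at a limit of 1.5 and 1 with agreeing spots, and 2 high genes became 1 among genes measured on all 5 arrays, 4 with ceiling spots kept and 0 with agreeing spots. Without centring fnr was at -1.64 in fnr flhDC and at -1.79 in fnr, and crp at 1.10 in the array labelled crp, or 0.94 when centred on all spots. Under deposited names the difference of 3 labelled and 2 unlabelled strains for the mot, tar and flhB operons, -0.17, turned to 0.14 without centring (exact permutation p = 0.7). As a mean over members it was -0.54 (exact permutation p = 0.1). It ranged from -0.25 to -0.09 with 1 array left out. For fnr flhDC minus fnr that list moved from -0.26 to -0.13 without centring and to -0.87 as a mean over members. Lists outside the middle 95% of random lists rose from 7 to 11 in the array labelled crp with means. With agreeing spots, Pearson correlations moved from 0.0190 to 0.0822 for crp and fnr flhDC and from 0.332 to 0.519 for fnr flhDC and fnr. With ceiling spots kept, they fell to 0.109 for the fnr pair and from 0.181 to -0.0101 for crp and fnr. With limma 0 lower genes became 6 without centring, with 1 higher gene, and 1 (wzyE) without fnr flhDC; no other array left out gave any. With placed genes limma called 0 lower genes with signs as deposited, and 1, cheA, with both crp arrays turned in sign; the turn was made after its values were seen, so that call is no test.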

Other observations

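All tests in this part were chosen after the results were seen, and the gene names below rest on an estimated order of spots, so they are hypotheses.

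Under that order, 98 of 150 position pairs of the creB flhDC and crp flhDC arrays could be placed, which named 2271 genes. Of these 98 pairs 70 held named genes and 71 were placed alike by the 2 separate comparisons, so the others rest on the combined score alone. In creB flhDC exactly 7 of the 2271 genes were at -1 or lower in both spots: creB itself (-1.66) and 6 genes that follow each other next to flhDC, motA (-1.76), motB (-2.84), cheA (-3.41), cheW (-3.76), tar (-3.45) and tap (-2.64). All 7 were among the 14 placed genes that had been left out of the scoring, though not out of the pairing of positions. The agreement of their 2 spots was thus not held out. The 6 measured neighbours of creB had a median of -0.15. The median from motA to tap was -3.12, consistent with a strain that lacks them besides creB.

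In crp flhDC the same genes were high as deposited: motA at 2.65, motB at 4.59, cheA at 4.10, cheW at 2.46 and tar at 1.67, while tap was at 0.23. Only casA joined these 5 among genes at 1 or higher in both spots, and 1 gene, endA, was at -1 or lower in both. The crp gene was 8th highest of 2268, at 1.01. The median from motA to tar was 2.65, which suggests that they are missing there too if mutant and wild type were exchanged between the dyes. On this reading the loss reached tap in creB flhDC and stopped between tar and tap in crp flhDC, as it did in fnr flhDC, where tap was at 0.12. On the far side of flhDC, otsB was at -0.14 in creB flhDC and 0.22 in crp flhDC. The positions of flhC, uspC and the genes from cheR to flhE could not be placed with confidence in these 2 arrays, so how far the losses extend was not analysed here.

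The fnr strain, labelled without flhDC, showed no low gene next to flhDC. The array labelled crp had none either, but there even the replaced crp gene stood at only 0.76. A missing gene in that array need thus pass neither -1 nor 1. With its sign turned, tap would be at -0.63 and the median of the mot, tar and flhB operons at -0.28. As deposited, the 5 genes from tar to motA lay between 0.13 and 0.35 there, below crp. In crp flhDC, under the estimated order of spots, all 5 lay above crp, at 1.67 to 4.59 against 1.01. In fnr flhDC they lay below fnr, at -1.58 or lower against -1.42. The values in the array labelled crp thus argue against such a loss of these 5 genes, with 1 array per strain. For the other genes next to flhDC, whether that strain lost any cannot be told from this array.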
